A study of Mus musculus with 8 samples.

How the data were processed

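Polyadenylated RNA from 8 flank tumors was sequenced with a stranded mRNA kit, per the labels' protocols. The tumors were 4 from vector control cells and 4 from Mcrs1-overexpressing cells, each from a separate mouse per the sample titles. Groups were taken from the titles, and mouse numbers serve as replicate names. No mouse number occurs in both groups, and the labels give no batch, date or litter, so no block or covariate was used. The labels name a single cell line and no separate derivations of the overexpressing cells, so p-values measure the spread between tumors, not between independently made lines.

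The authors deposited whole-number counts per Ensembl gene for each tumor. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1 and the genome build GRCm38 were used. The strand setting, the annotation release and the treatment of reads that match several genes are not given in the sources used here, so near-identical and overlapping genes are uncertain. The authors also deposited a table of log2 fold changes and mean log2 expression, with p-values and adjusted p-values from limma, which the submitters' processing notes name together with R 4.2.1. That table has 18392 rows for 18313 genes. It was used only for comparison, and its filter and design are not given in the sources used here.

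The count table holds 43432 gene IDs, of which 42462 were matched to symbols and GRCm38 positions in GENCODE M21 and 970 were left without a symbol. The authors' symbols equaled those of GENCODE M21 for 98.0% of the IDs compared. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 15456 genes. Libraries were scaled with TMM, and Mcrs1ox was compared with Control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Group levels are CPM with TMM library sizes, as mean ± SD over 4 tumors, and log2 CPM used a prior count of 2.

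Before the data were examined, 46 gene lists were written, 25 for pathways and complexes and 21 for cell types. Of 752 listed members, 5 had no match. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 45 lists that had at least 2 measured members. The pancreatic acinar list had 1 measured member and was not tested. Camera with an estimated correlation and fry were run as alternatives. Members are counted as higher or lower by the edgeR test over all genes, and again adjusted over the list alone. The lists described by their members were picked in part after results were seen: the hypoxia, mesenchymal transition, nucleic acid sensing, MYC, oxidative phosphorylation and plasma cell lists because camera called them, and the mast cell and ductal lists, which it did not call, because single members stood out.

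Genes are named by a rule fixed before the data were examined. It takes Mcrs1, and the 10 largest rises and falls among genes past the threshold with an average log2 CPM of at least 1 and no overlap between groups. It leaves out gene models without a symbol and immunoglobulin or T cell receptor segments. It then takes up to 4 members with the smallest p of each list described, and H2-K1, H2-D1, B2m, Tap1, Nlrc5, Cd274, Cd8a, Gzmb and Ifng whatever their result. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

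Single values were compared with exact two-sided permutation tests over the 70 assignments of 4 of 8 tumors. Tumors of a group were compared in pairs, and their counts differed by far more than sampling noise, with a mean chi-square per gene of 12.9 to 18.7 between Control tumors and 34.5 to 70.2 between Mcrs1ox tumors, so all 8 were kept as separate samples. Chromosome medians were taken over 12897 autosomal and X-linked genes with an average log2 CPM of at least 1.

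The gene test was tested on simulated data: counts for 15268 tested genes with the tumors' means and library sizes and 200 changed genes. It recovered 28.4% of 67 genes changed 1.5-fold, 56.7% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, all in the right direction, and 8.06% of its calls were false, above the nominal rate. Changes under 2-fold were therefore often missed in the simulation. In the tumors 2633 genes were called, which makes the adjusted threshold less strict there, so these recovery rates do not carry over to the tumors. A simulated raised list and a simulated lowered chromosome were called, and no other list or chromosome was. Simulated genes varied independently of each other, whereas the estimated correlation within the MHC class I list of the tumors was 0.718. The simulation therefore does not show how often the list and chromosome tests call falsely in the tumors.

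Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, total counts only, no filter, a filter of at least 1 CPM in 4 tumors, limma-voom with and without sample weights, DESeq2 1.42.0, robust dispersion, 1 surrogate variable from sva 3.50.0, each tumor left out in turn, and a library size without mitochondrial, hemoglobin, muscle, fat and skin genes. A 2-fold minimum and an adjusted p threshold of 0.01 were also applied. Subtracting chromosome medians and leaving out Mcrs1ox tumors 13 and 18 together were chosen after seeing the data.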

Results

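Gene expression was measured by RNA sequencing in 8 subcutaneous mouse tumors grown from HT cells, a mouse pancreatic cancer line per the labels. In 4 tumors the injected cells carried a vector control (Control, mice 1 to 4), and in 4 they overexpressed Mcrs1 (Mcrs1ox, mice 13, 17, 18 and 24). Each tumor came from a separate mouse, and tissue was taken 4 weeks after 1000000 cells were injected. A bulk tumor library holds cancer cells together with host immune, vascular and stromal cells. The libraries held 19459858 to 23203296 counts, on average 21186008 ± 1648408 in Control and 20496928 ± 1560357 in Mcrs1ox tumors (SD, n = 4 each). The comparison asked which genes respond in tumors to overexpression of Mcrs1, a subunit of the NSL histone acetyltransferase complex and of the INO80 chromatin remodeling complex.

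Mcrs1 itself lay at 68.1 ± 7.75 CPM in Control and 85.8 ± 16.7 CPM in Mcrs1ox tumors (SD, n = 4 each), where CPM is the count relative to the scaled library size. The log2 fold change was 0.33 (SE 0.15), and it did not pass the threshold over all genes in edgeR's quasi-likelihood test (adjusted p = 0.144). The exact two-sided permutation test of log2 CPM gave p = 0.114, where the smallest p that 4 against 4 tumors allow is 0.0286. The groups overlapped: Mcrs1ox tumors 13 and 24 had 67.0 and 76.8 CPM, beside 60.5 to 75.1 CPM in the Control tumors. Host cells add reads from their unmodified Mcrs1, so the level in the cancer cells alone was not measured. Whether reads of the introduced Mcrs1 sequence fall within the counted gene model is not given in the sources used here. Mcrs1 (ENSMUSG00000037570) lies on chromosome 15, 99242817 to 99251961 in GRCm38. It passed the threshold, with a log2 fold change of 0.50 and adjusted p = 0.0491, once chromosome-wide shifts, described further on, were subtracted. That alternative was chosen after the data were seen, and Mcrs1 passed in no other. It applied the chromosome 15 median of -0.17 to all Mcrs1ox tumors. Tumor 18, with the most Mcrs1 (102.6 CPM), had a chromosome 15 median of 0.05. The authors' deposited table gives Mcrs1 a log2 fold change of 0.316 with an adjusted p of 0.143.

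Across the genome, 1415 genes were higher and 1218 were lower in Mcrs1ox tumors among 15456 genes tested (edgeR, adjusted p under 0.05), and 622 and 391 of these changed at least 2-fold. In 3547 tested genes, or 22.9%, all 4 tumors of a group lay above all 4 of the other, where chance gives 2.86%. The first principal component of log2 CPM held 48.9% of the variance and separated the groups. On the second, with 15.5%, Mcrs1ox tumors 13 and 24 lay at 32.5 and 32.2 and tumors 17 and 18 at -35.3 and -30.6. The mean log2 CPM of the skin list, against the Control mean, was 2.07 and 1.32 in tumors 13 and 24 and -1.26 and -1.35 in tumors 17 and 18, and between -1.38 and 1.23 in the Control tumors. The counts of genes higher and lower fell to 893 and 760 without Control tumor 1 and to 744 and 655 without Control tumor 2, and that of genes lower to 720 without Control tumor 4. The authors' deposited table lists 1295 genes higher and 1398 lower at an adjusted p under 0.05, and among the 15419 genes tested in both analyses 2386 were called in both.

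The genes with the largest rise were of several kinds. Lypd8, a surface protein of colonic epithelium, rose from 0.521 ± 0.338 to 45.6 ± 28.7 CPM, a log2 fold change of 6.44 (SE 0.59, adjusted p = 0.000328). Cftr, the epithelial chloride channel, rose from 4.51 ± 4.55 to 126 ± 98.4 CPM, and the membrane mucin gene Muc3 rose by a log2 fold change of 4.32. The growth factor gene Bmp8b (log2 fold change 4.91), the homeobox gene Hoxa13 (4.83), the potassium channel gene Kcnk1 (4.37) and the Myc relative Bmyc (4.38) rose with them, as did Zfp185 (5.04), Tmem246 (4.59) and the scaffold gene Homer2 (4.52). All 10 were above the Control range in all 4 Mcrs1ox tumors and past the threshold, as the rule that picked them requires, with adjusted p between 0.000216 and 0.00402.

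The largest falls were in a mixed group. The serotonin receptor gene Htr1b fell from 12.4 ± 2.32 to 0.251 ± 0.236 CPM, and the hyaluronan synthase gene Has2 from 69.2 ± 26.4 to 4.11 ± 4.47 CPM. Mycn, a transcription factor of the Myc family, fell from 32.0 ± 2.38 to 1.59 ± 2.88 CPM, with 5.91 CPM in Mcrs1ox tumor 13 and no more than 0.157 CPM in the other Mcrs1ox tumors. Palm3 (log2 fold change -5.51), Tmem150c (-4.36) and Morc4 (-4.21) were also among the largest falls. The granzyme genes Gzmf (-5.17), Gzmg (-4.90) and Gzmd (-4.33), proteases of cytotoxic lymphocyte granules, were in this group too, with adjusted p of 0.00699, 0.00421 and 0.00600. They are near-identical neighbors on chromosome 14, so the division of reads among them is uncertain, and all 3 calls were lost in limma-voom with sample weights, that of Gzmf also without weights.

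MHC class I antigen presentation genes rose together in Mcrs1ox tumors. Of 23 measured members, 22 were higher and none lower, also when adjusted over the list alone, with a median log2 fold change of 1.10. H2-K1 rose from 462 ± 105 to 1267 ± 377 CPM and H2-D1 from 444 ± 94.0 to 1187 ± 243 CPM, both encoding class I heavy chains, and their light chain gene B2m rose from 313 ± 39.6 to 640 ± 98.4 CPM (n = 4 each). Tap1, the peptide transporter, rose with a log2 fold change of 2.14 (SE 0.26), the immunoproteasome subunit gene Psmb8 with 2.73 (SE 0.29), the peptide-trimming protease gene Erap1 with 1.00 (SE 0.08) and the class I gene H2-Q7 with 2.04 (SE 0.18). Nlrc5, the transactivator of class I genes, had a log2 fold change of 0.92 (adjusted p = 0.0363), and its call was lost without Control tumor 1, 2 or 4 or Mcrs1ox tumor 13 or 24, where adjusted p reached 0.102. All 11 MHC class II members rose, with a median of 1.42 and the same count when adjusted over the list alone, among them the transactivator gene Ciita (1.75), the invariant chain gene Cd74 (1.41), H2-DMa (1.67) and H2-Eb1 (1.19). Both lists were called higher by camera with its preset correlation (adjusted p = 4.55e-15 and 5.78e-09), and neither with an estimated one (adjusted p = 0.374 and adjusted p = 0.298 with an estimated correlation). T cell and dendritic cell markers rose in the same tumors, with list medians of 1.69 and 1.11, and the pan-leukocyte gene Ptprc, chosen after its values were seen, was 1.67-fold higher. H2 class I paralogs are closely similar in sequence, and how shared reads were counted is not given in the sources used here.

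Interferon response genes were higher in Mcrs1ox tumors. In the interferon-gamma list, 19 of 20 measured members were higher and none lower, with a median log2 fold change of 2.12 and the same count adjusted over the list alone. The tryptophan-degrading enzyme gene Ido1 rose from 2.06 ± 1.19 to 26.9 ± 6.56 CPM (SD, n = 4 each), and the interferon-inducible GTPase genes Gbp3 and Gbp7 by log2 fold changes of 2.32 and 2.10. In the type I interferon list, 21 of 24 members were higher (23 when adjusted over the list alone), with a median of 1.68; the antiviral genes Oas3 (2.58), Oasl2 (1.91), Rtp4 (1.81) and Xaf1 (1.51) had the smallest p. Among nucleic acid sensing genes 5 of 11 rose, also when adjusted over the list alone, including the cytosolic DNA sensor gene Aim2 (2.16), the RNA receptor gene Tlr3 (1.03), Ikbke (1.00) and Ifi204 (0.79). Camera called the 3 lists higher (adjusted p = 7.3e-16, 2.2e-19 and 0.000541), and none with an estimated correlation (adjusted p = 0.298 with an estimated correlation for each). T cell markers rose in the same 4 tumors, with a list median of 1.69. Ifng, the gene of interferon-gamma, was too low for the filter and stood at 0.0467 ± 0.0401 CPM in Control and 0.728 ± 0.583 CPM in Mcrs1ox tumors, with no overlap (exact permutation p = 0.0286, the smallest possible).

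**Figure D1:**
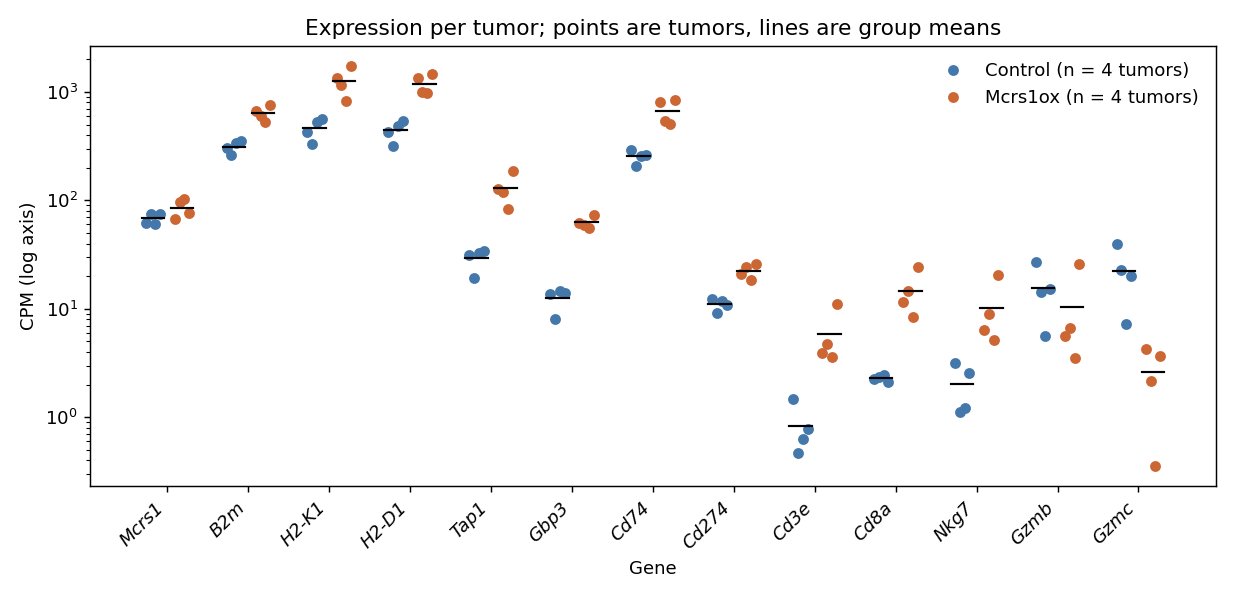
CPM on a log axis for 13 genes, with a point for each tumor and a line at each group mean (n = 4 tumors per group). H2-K1 lay between 827 and 1735 CPM in the Mcrs1ox tumors and between 333 and 567 CPM in the Control tumors, while the groups overlapped for Mcrs1 and Gzmb.

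T cell markers were higher in Mcrs1ox tumors. Of 18 measured T cell genes, 12 rose over all genes tested and 18 when adjusted over the list alone, with a median log2 fold change of 1.69. The T cell receptor complex genes Cd3e and Cd3g rose from 0.835 ± 0.441 to 5.82 ± 3.50 CPM and from 1.35 ± 0.351 to 8.05 ± 4.01 CPM, and Lck, the kinase of T cell receptor signaling, and the surface receptor gene Cd6 by log2 fold changes of 1.60 and 1.80. The CD8 chains Cd8a and Cd8b1 both rose, also when adjusted over the list alone; Cd8a went from 2.30 ± 0.147 to 14.6 ± 6.78 CPM (log2 fold change 2.67, adjusted p = 0.000856). Of 11 dendritic cell genes, 6 rose (9 rose and 1 fell when adjusted over the list alone), among them Clec9a (2.31) and Xcr1 (2.07), markers of cross-presenting dendritic cells, and the integrin gene Itgae (1.66). Cd8a, also counted in the CD8 list, is 1 of these 6. The CD4 and regulatory T cell list was not called (camera adjusted p = 0.243): 1 of 7 members rose, the same when adjusted over the list alone, and Cd4, named after its values were seen, lay at 2.44 ± 0.137 and 3.53 ± 1.39 CPM. Camera called the T cell, CD8 and dendritic cell lists higher (adjusted p = 1.1e-09, 0.00534 and 5.93e-05), and none of them with an estimated correlation (adjusted p = 0.374, adjusted p = 0.339 and adjusted p = 0.298 with an estimated correlation). Ptprc, the gene of CD45, rose from 26.8 ± 2.63 to 44.7 ± 8.29 CPM.

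Cytotoxic effector genes moved in both directions. Of 13 measured members, 5 rose and 2 fell over all genes tested, and 5 rose and 3 fell when adjusted over the list alone; the list was not called (camera adjusted p = 0.221). The granule protein gene Nkg7 and the transcription factor gene Tbx21 rose by log2 fold changes of 2.34 and 2.32. Eomes, a related transcription factor of cytotoxic lymphocytes, fell from 5.85 ± 1.13 to 1.12 ± 0.413 CPM, and the granzyme gene Gzmc from 22.4 ± 13.3 to 2.61 ± 1.75 CPM, the latter not past the threshold in limma-voom with sample weights. Gzmb, the granzyme most used as a marker of killing, lay at 15.6 ± 8.84 and 10.4 ± 10.3 CPM (adjusted p = 0.557), and its 95% interval spanned 0.253-fold to 1.75-fold. Mcrs1ox tumor 24 had 25.7 CPM of Gzmb and the other Mcrs1ox tumors 3.51 to 6.70 CPM, and without tumor 24 the log2 fold change was -1.56 (adjusted p = 0.0563). Immune checkpoint genes were called higher (camera adjusted p = 2.78e-06, adjusted p = 0.0840 with an estimated correlation), with 8 of 16 up and 10 up when adjusted over the list alone. Pdcd1, the gene of PD-1, rose from 0.694 ± 0.443 to 5.84 ± 2.77 CPM, its ligand gene Cd274 from 11.1 ± 1.37 to 22.4 ± 3.47 CPM, Tox, a factor of exhausted T cells, by a log2 fold change of 3.46 and the inhibitory receptor gene Btla by 1.79. Of 23 chemokine genes, 10 rose, or 12 when adjusted over the list alone, including Ccl20 (2.91), Xcl1 (1.58) and Cxcl16 (0.71), and camera called the list higher (adjusted p = 0.000864, adjusted p = 0.542 with an estimated correlation). The Cxcl16 call was lost once chromosome-wide shifts were subtracted.

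Genes of epithelial identity and cell division were higher. Of 18 epithelial members, 7 rose over all genes tested, and 10 rose and 1 fell when adjusted over the list alone. Against the Control mean, the mean log2 CPM of the list was 1.45 in Mcrs1ox tumor 13, 0.20 in tumor 17, 0.63 in tumor 18 and 0.65 in tumor 24, with 0.19 in Control tumor 4. The tight junction genes Ocln and Cldn7 rose from 5.98 ± 1.05 to 29.6 ± 6.68 CPM and from 7.72 ± 2.01 to 33.7 ± 7.85 CPM, and the keratin genes Krt19 and Krt7 by log2 fold changes of 1.11 and 1.26. Of 30 proliferation genes, 12 rose, or 15 when adjusted over the list alone, with a median of 0.37. The mitotic cyclin gene Ccnb2 rose from 24.2 ± 1.52 to 57.3 ± 4.54 CPM, and Birc5 (0.80), Mcm3 (0.83) and Pcna (0.54) rose with it. Over all genes tested 18 did not pass, among them Mki67 (0.23, adjusted p = 0.332). The proliferation list's mean was 0.13 above the Control mean in Mcrs1ox tumor 24 and 0.30 to 0.61 in the other Mcrs1ox tumors, beside 0.08 in Control tumor 1. Of 20 MYC and ribosome biogenesis targets, 4 rose, among them Nop58 (0.38), and of 20 cholesterol biosynthesis genes 5 rose, or 6 when adjusted over the list alone, including Mvk (0.63) and Cyp51 (0.82), a mevalonate kinase and a sterol demethylase. The cholesterol list's mean was 0.45 and 0.63 above the Control mean in Mcrs1ox tumors 17 and 18, and 0.08 and 0.07 in tumors 13 and 24, beside 0.04 in Control tumor 3. Camera called these 4 lists higher (adjusted p = 0.000864, 4.73e-07, 0.00709 and 0.000864), and none with an estimated correlation (adjusted p = 0.476, adjusted p = 0.542, adjusted p = 0.374 and adjusted p = 0.653 with an estimated correlation). The MYC count was the same when adjusted over the list alone. The calls of all 4 MYC targets that rose, Nop58 among them, were lost once chromosome-wide shifts were subtracted. Srm, 1 of these, lies on chromosome 4, whose median was only 0.03. Its call was also lost in 6 of the 8 fits that left out 1 tumor, and that of Nme1 in 7 (adjusted p up to 0.108 and 0.129). The Ncl call was lost without Control tumor 1 (adjusted p = 0.0507).

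Matrix, mesenchymal, hypoxia and early response lists were lower, each through few members. Among all 15456 genes tested, 1218 were lower. The median log2 fold change was -0.35 for the mesenchymal, -0.12 for the hypoxia and -0.37 for the early response list. The means of the mesenchymal and hypoxia lists overlapped between the groups (exact permutation p = 0.0571 each). Of 23 extracellular matrix genes, 4 fell, or 8 when adjusted over the list alone, with a median of -0.45: Has2, the collagen VI gene Col6a1 (-0.67), the basement membrane gene Nid1 (-1.12) and Col6a3 (-0.62), whose call was lost without Control tumor 1 or 2 or Mcrs1ox tumor 13, 17 or 18 (adjusted p up to 0.119). The matrix list's mean log2 CPM, against the Control mean, was -1.01 and -0.92 in Mcrs1ox tumors 17 and 18 and -0.30 and -0.38 in tumors 13 and 24, beside -0.23 in Control tumor 4. The mean of the fibroblast list was -0.83 and -0.27 in Mcrs1ox tumors 17 and 18 and 0.30 and 0.50 in tumors 13 and 24. Of 21 mesenchymal transition genes, 3 fell, or 4 when adjusted over the list alone. The transcription factor gene Zeb1 fell from 93.4 ± 6.43 to 56.1 ± 12.6 CPM and the cadherin gene Cdh2 from 181 ± 16.2 to 103 ± 36.6 CPM, a call lost without any 1 Control tumor or Mcrs1ox tumor 13 or 24 (adjusted p up to 0.0845). The Zeb1 and Cdh2 calls were also lost once chromosome-wide shifts were subtracted. Of 25 hypoxia and glycolysis genes, 3 fell, the same when adjusted over the list alone: Egln3, an oxygen-sensing hydroxylase, from 162 ± 28.8 to 13.8 ± 17.3 CPM, the stress response gene Ndrg1 (-0.89) and the mTORC1 inhibitor gene Ddit4 (-0.49). Of 20 early response and heat shock genes, 5 fell, or 6 when adjusted over the list alone, with Dusp1 (-1.18), Fosb (-1.35), Hspa1a (-2.16) and Hspa1b (-1.47) leading; the last 2 are near-identical copies, and the Hspa1b call was lost with sample weights. Camera called these 4 lists lower (adjusted p = 0.000841, 0.00622, 0.0289 and 0.0265), and none with an estimated correlation (adjusted p = 0.542, adjusted p = 0.542, adjusted p = 0.674 and adjusted p = 0.646 with an estimated correlation). The hypoxia call was lost without Control tumor 3 or 4 or Mcrs1ox tumor 13 or 18 (adjusted p up to 0.118), and the early response call without Control tumor 4 or Mcrs1ox tumor 18 (adjusted p up to 0.117).

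Of the 8 NSL complex partners of Mcrs1, 3 fell slightly, or 4 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.118, adjusted p = 0.646 with an estimated correlation), while fry called it lower (adjusted p = 0.0456). The mean of its members separated the groups (exact permutation p = 0.0286, the smallest possible). Phf20, a chromatin reader of the complex, fell from 80.9 ± 9.91 to 57.9 ± 2.83 CPM, and Kansl2 and Ogt had log2 fold changes of -0.30 each. The Kansl2 call was lost without any 1 tumor except Mcrs1ox tumor 18, and the Ogt call without any 1 Control tumor or Mcrs1ox tumor 13 (adjusted p up to 0.120 and 0.0916). Both calls were also lost without the filter, and that of Kansl2, on chromosome 15, once chromosome-wide shifts were subtracted or with the library size that leaves out mitochondrial, hemoglobin, muscle, fat and skin genes. Kat8, the acetyltransferase of the complex, had a log2 fold change of -0.38 (adjusted p = 0.0822). Of 14 INO80 complex members 1 rose, also when adjusted over the list alone, and that list was not called (camera adjusted p = 0.997).

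**Figure D2:**
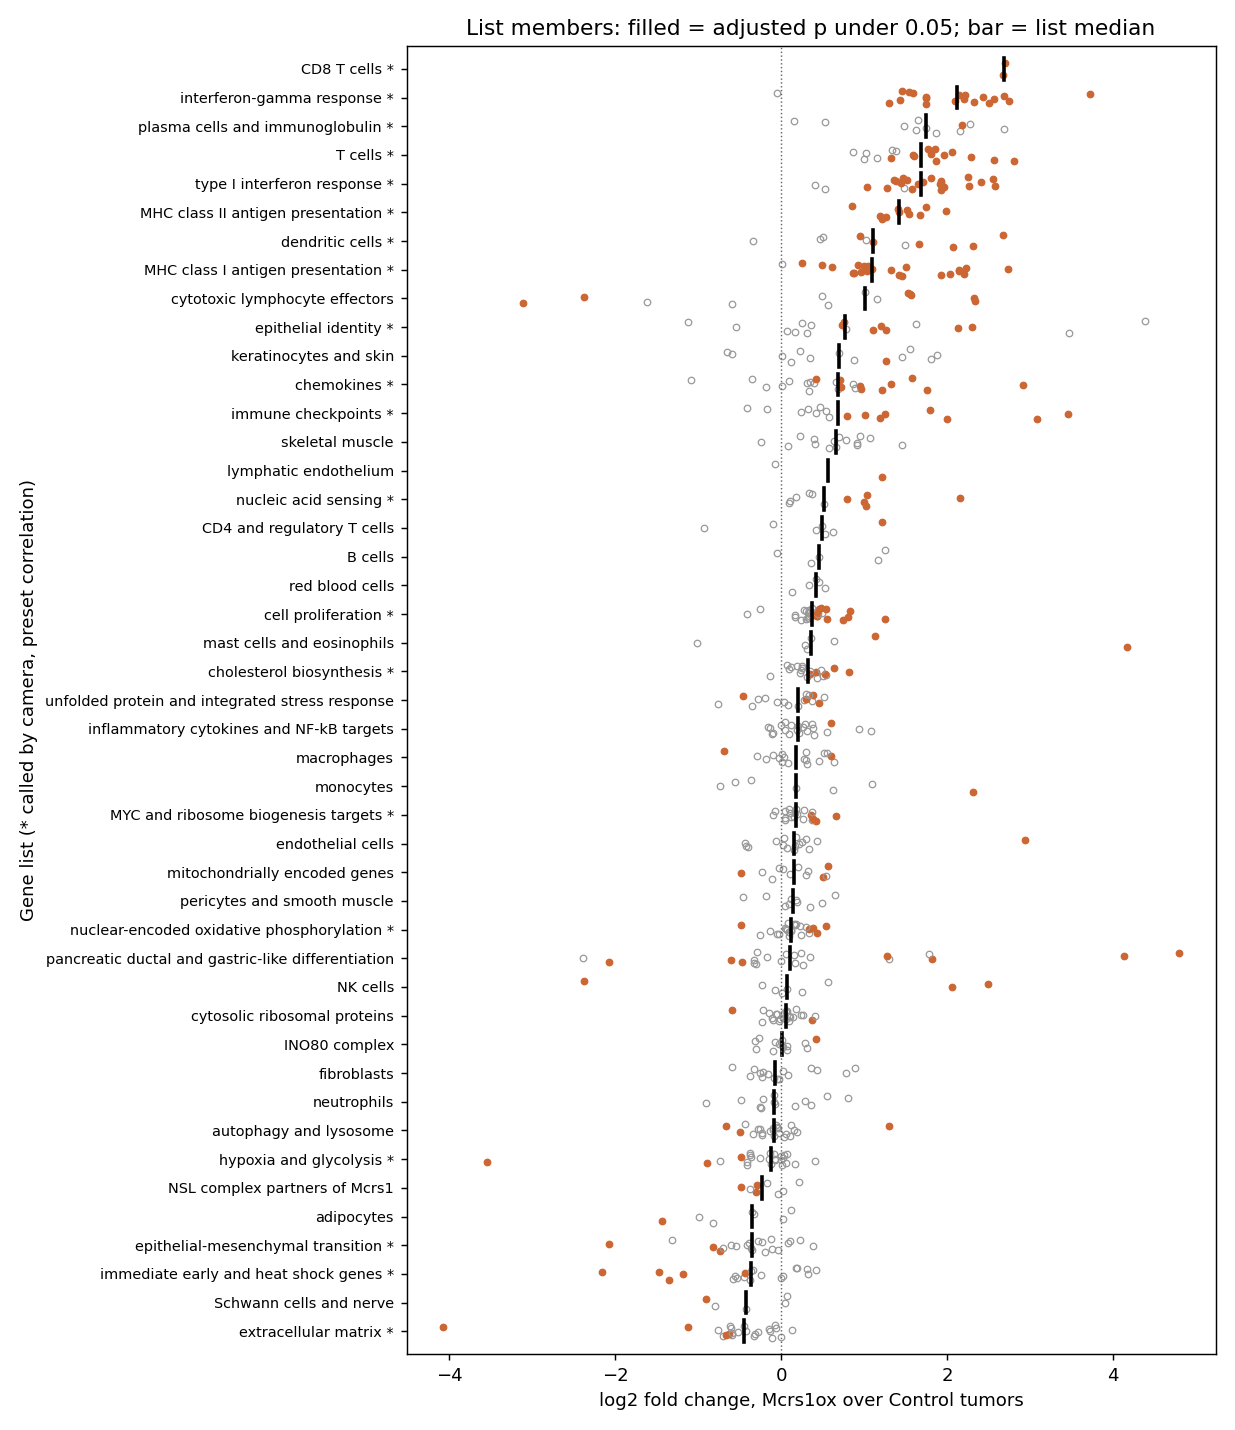
Log2 fold changes, Mcrs1ox over Control tumors, of the measured members of the 45 lists tested, with filled points for members at adjusted p under 0.05 (edgeR), a bar at each list median and an asterisk for lists called by camera with its preset correlation. The interferon-gamma median lies at 2.12 and the extracellular matrix median at -0.45.

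In all, camera called 16 of 45 lists higher and 4 lower with its preset correlation, and 0 in either direction with an estimated correlation, while fry called 12 higher and 1 lower. The list that fry called lower was that of the NSL partners, and none of the 4 lists that camera called lower passed fry (adjusted p between 0.0572 and 0.218). The mean of the members separated the groups in 13 of the 16 lists called higher and 2 of the 4 called lower (exact permutation p = 0.0286 each, the smallest possible). Other divisions of the 8 tumors into 4 and 4 called up to 24 lists with the preset correlation.

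Some chromosomes differed in median between the groups. The median log2 fold change of the 327 expressed genes on chromosome 18 was -0.51, and 83.2% of them were lower in Mcrs1ox tumors. Against the Control mean, the chromosome 18 median was -0.51, -0.34, -0.66 and -0.52 in Mcrs1ox tumors 13, 17, 18 and 24, and between -0.08 and 0.08 in the Control tumors. Chromosome 1 had a median of 0.26 over 777 genes, and chromosome 11 a median of 0.19 over 1101 genes, which was 0.04 in Mcrs1ox tumor 18. Chromosome 15, which carries Mcrs1, had a median of -0.17 over 508 genes, with 71.7% of them lower, but 0.05 in Mcrs1ox tumor 18. Chromosome 18 held 2.54% of the 12897 genes compared and 16.7% of those called lower, and chromosomes 1 and 11 held 14.6% of the genes compared and 33.6% of those called higher. The exact permutation test of the medians gave p = 0.0286 for chromosomes 18 and 1, the smallest possible, p = 0.0571 for chromosome 11 and p = 0.143 for chromosome 15, but also p = 0.0286 for chromosome 2, whose median was 0.05. Camera with its preset correlation called chromosomes 18 and 15 lower (adjusted p = 6.66e-23 and 9.22e-06) and chromosomes 1 and 11 higher (adjusted p = 2.57e-09 and 9.12e-07), and also chromosomes 8 and 12 lower (adjusted p = 0.0138 and 0.00138). It called none with an estimated correlation (adjusted p = 0.54 with an estimated correlation for chromosome 18 and adjusted p = 0.795 for chromosomes 1, 11 and 15). With these shifts subtracted, an alternative chosen after the data were seen, 1076 genes were higher and 949 lower.

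**Figure D3:**
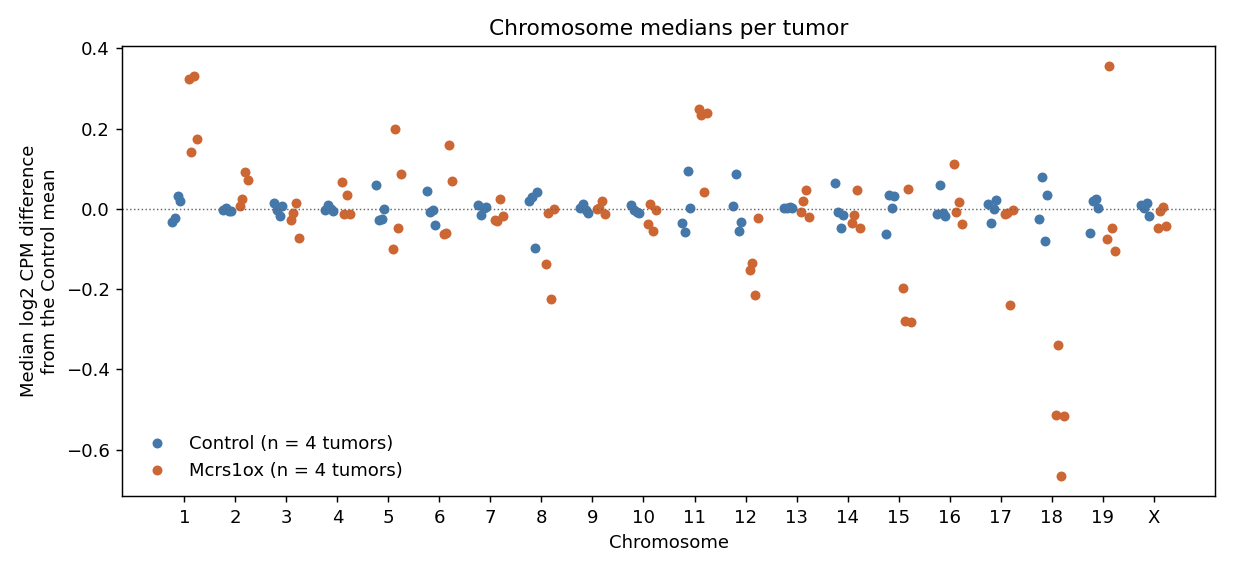
Median log2 CPM difference from the Control mean over the expressed genes of each chromosome, with a point for each tumor (n = 4 per group). On chromosome 18 the 4 Mcrs1ox tumors lie between -0.66 and -0.34, all below the Control tumors.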

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

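Values of the named genes and of the libraries were compared within its group of 4 tumors, and a tumor was singled out where its gap to the nearest other tumor, divided by the group's whole range (log2 CPM for genes), exceeded Dixon's 95% critical value for 4 samples. Of 267 groups of values, 12 had such a tumor, and chance gives about 1 in 20, so 12 is no more than chance gives. Among genes near the center of the comparison, Control tumor 2 was low for Tap1 (19.1 CPM against 31.0 to 33.9 in the other Control tumors, gap ratio 0.845), Gbp3 (7.97 against 13.8 to 14.7 CPM, 0.887) and Aim2 (5.05 against 18 to 21.5 CPM, 0.877). Mycn stood at 5.91 CPM in Mcrs1ox tumor 13 and at 0.133 to 0.157 CPM in the other Mcrs1ox tumors (gap ratio 0.970). Bmyc was high in Mcrs1ox tumor 24 (13.4 against 6.26 to 7.12 CPM, 0.832), where Nid1 was low (126 against 238 to 267 CPM, 0.846). Kat8 was high in Mcrs1ox tumor 13 (13.8 against 10.9 to 11.2 CPM, 0.879), and Dhcr7 in Mcrs1ox tumor 18 (42.7 against 36.1 to 36.6 CPM, 0.912). Control tumor 1 was high for Eomes (7.54 against 5.21 to 5.42 CPM, 0.892) and low for Onecut2, a transcription factor of liver and pancreas (850 against 1020 to 1050 CPM, 0.849). The library of Mcrs1ox tumor 18 held 22824031 counts beside 19492640 to 19886591 in the other Mcrs1ox libraries (0.882), and the 20 most abundant genes took 8.26% of the counts in Control tumor 4 beside at most 8.02% in the other Control tumors (0.923).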

How the results depend on the processing

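The alternatives that subtract chromosome shifts or leave out Mcrs1ox tumors 13 and 18 together were chosen after seeing the data. None of the 20 called lists changed direction. Among genes called both in the main test and in an alternative, 0 changed sign, which genes called from the same tumors could hardly do. Of the 2633 genes called in the main test, 1377 were called again without Control tumor 2 and 1600 without Control tumor 1, with fewer samples. Of 110 named genes past the threshold, many of them named for a large change or a small p, 86 stayed past it in every alternative run. The other 24 did not in at least 1. With each tumor left out in turn, genes higher ranged from 744 to 1666, genes lower from 655 to 1342, and lists called lower from 2 to 4, with fewer samples in each such fit. A 2-fold minimum left 622 genes higher and 391 lower, and an adjusted p under 0.01 left 563 and 450, as stricter thresholds must. Camera with an estimated correlation called 0 lists higher and 0 lower, where edgeR called 2633 genes and fry called 12 lists higher and 1 lower (the cause was not tested). The estimated correlation was 0.718 for the MHC class I list, 0.601 for interferon-gamma and 0.611 for T cells, against the preset 0.01. For the immune checkpoint list it was 0.00365, below the preset value. That list was not called either (camera adjusted p = 0.0840 with an estimated correlation, 2.78e-06 with the preset one), so a higher correlation does not explain its lost call. The list fry called lower was that of the NSL partners, and all 4 lists called lower by camera lost their call in fry. Without Mcrs1ox tumors 13 and 18 together, 2 lists were lower, Gzmb had a log2 fold change of 0.058 (-0.59 in the main test, and -1.56 without tumor 24) and Epcam one of -0.90, with fewer samples. With each tumor left out, Epcam ranged from -1.25 to 4.12 and turned only without Mcrs1ox tumor 13, which held 62.3 CPM against at most 3.05 CPM in the others. Xist ranged from -0.28 to 0.050 and the Y-linked Kdm5d from -0.20 to 0.0048, and the cause was not tested. None of these 3 genes passed the threshold with all 8 tumors. With chromosome shifts subtracted, Mcrs1 had a log2 fold change of 0.50 and passed the threshold (adjusted p = 0.0491, between 0.0491 and 0.333 over its 21 alternatives), since its chromosome 15 has a median of -0.17, and the chromosome 18 gene Atp5a1, an ATP synthase subunit called lower in the main test, turned to 0.029, its chromosome having a median of -0.51. The scalings, other tests and left-out tumors kept the share of higher among called genes between 50.4% and 56.7% (53.7% in the main test), and a 2-fold minimum gave 61.4%. Genes such as Ifng, with under 1 CPM in both groups, are limited by depth, and Ifng passed the edgeR test without the filter (adjusted p = 0.00763).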

Other observations

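The tests of chromosome-wide shifts in the interferon rise, of random gene sets, of the parts of chromosome 18, of mitochondrial mRNAs, of carry-over as the whole cause and of runs of neighboring genes were chosen after the results were seen. In the lists described next, few members passed the threshold. The plasma cell and immunoglobulin list was called higher by camera (adjusted p = 0.00534, adjusted p = 0.646 with an estimated correlation) with a median log2 fold change of 1.75, but 1 of 11 members passed, Ighm, the mu heavy chain, which rose by a log2 fold change of 2.18 (SE 0.45, adjusted p = 0.0103). Igkc ranged from 1.11 to 115 CPM in Control and from 29.9 to 302 CPM in Mcrs1ox tumors, with the highest Control value in tumor 3. Without Control tumor 3, Igkc (log2 fold change 4.99, adjusted p = 0.0109), Jchain (4.27, adjusted p = 0.0158), Pou2af1 (2.62, adjusted p = 0.0412) and Ighg1 (adjusted p = 0.00574) also passed. The oxidative phosphorylation list was called higher (adjusted p = 0.0380, adjusted p = 0.653 with an estimated correlation) with a median of 0.12, 4 of 25 members up, among them Cox5b (0.54), and Atp5a1 down (-0.48). Neither gene stayed past the threshold once chromosome-wide shifts were subtracted, and the list's call was lost without Control tumor 1, 2 or 3 or Mcrs1ox tumor 24 (adjusted p up to 0.124). Mcpt4, a protease of connective tissue mast cells, rose from 6.27 ± 2.71 to 113 ± 72.2 CPM (SD, n = 4 each), while the mast cell list was not called (camera adjusted p = 0.163) and Tpsab1 and Cma1, other mast cell proteases, did not pass (log2 fold changes -1.02 and 0.63). In the ductal and gastric list, also not called (camera adjusted p = 0.746), 4 of 22 members rose and 3 fell: Agr2, a secretory pathway protein, rose from 2.46 ± 2.28 to 43.2 ± 35.3 CPM, and the endoderm factor Foxa1 fell from 15.3 ± 2.17 to 3.62 ± 0.747 CPM.

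Most host cell lists outside the report were not called by camera. Macrophage (median 0.18, adjusted p = 0.244), monocyte (0.17, adjusted p = 0.435), neutrophil (-0.08, adjusted p = 0.781), NK cell (0.07, adjusted p = 0.781), B cell (0.45, adjusted p = 0.548), fibroblast (-0.07, adjusted p = 0.60), endothelial (0.16, adjusted p = 0.270) and pericyte (0.14, adjusted p = 0.50) lists lay closer to 0 than the T cell list. Skin (0.70, adjusted p = 0.749), skeletal muscle (0.66, adjusted p = 0.263) and adipocyte (-0.35, adjusted p = 0.166) lists were not called either, nor were lymphatic endothelium (0.57, adjusted p = 0.562), red blood cells (0.42, adjusted p = 0.687) and Schwann cells (-0.42, adjusted p = 0.233). The same held for the lists of inflammatory cytokines (0.21, adjusted p = 0.202), autophagy and lysosome (-0.09, adjusted p = 0.270), the unfolded protein response (0.21, adjusted p = 0.219), mitochondrially encoded genes (0.15, adjusted p = 0.435) and ribosomal proteins (0.05, adjusted p = 0.746).

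Some genes stood out in a single tumor and were chosen after their values were seen. Epcam, an epithelial adhesion gene, was at 62.3 CPM in Mcrs1ox tumor 13 and at most 3.05 CPM in the other tumors, and Prom1, a membrane protein gene, at 118 CPM there and at most 5.02 CPM elsewhere. In Mcrs1ox tumor 18, 5 consecutive expressed genes on chromosome 8, from 8617434 to 10039072 in GRCm38, exceeded the highest of the other 7 tumors by 1.68-fold or more. This run was found by inspection and the bound of 1.5-fold was set afterwards; with that bound, a search of all chromosomes in all 8 tumors found 6 runs of at least 3 genes, of which this was the longest, followed by Gzmd, Gzmg, Gzmf and Gzmc in Control tumor 1. The ephrin gene Efnb2 had 1200 against 195 CPM, Arglu1 459 against 92.8 CPM, Abhd13 223 against 58.2 CPM and the DNA ligase gene Lig4 71.1 against 21.9 CPM. Xist, the transcript of the inactive X chromosome, lay between 2775 and 5498 CPM over the 8 tumors, and the Y-linked genes Ddx3y between 5.76 and 11.4 CPM and Kdm5d up to 3.82 CPM. None of them passed the edgeR test between groups (adjusted p = 0.810, 0.449 and 0.753), and neither did Uty, also Y-linked (log2 fold change 0.43, adjusted p = 0.208), although its groups did not overlap.

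Of the 35 divisions of the 8 tumors into 4 and 4, only 1, the real one, called as many as 2633 genes, and the highest count among the others was 0. That argues against chance division for the gene count but does not exclude it, since 1 of 35 is the smallest share possible. Every other division mixes the groups, so the group difference enters its residual spread and lowers its count. For the lists chance division stays open: 6 of the 35 divisions, the real one included, called at least 20 lists, and the highest of the others called 24. Divisions that keep most tumors of a group together retain part of the group difference, so their list counts are not a pure reference for chance.

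A candidate explanation for the rise of interferon and MHC class I genes is a higher share of leukocytes in Mcrs1ox tumors. If leukocytes of unchanged profile were the cause, genes restricted to leukocytes would rise at least as much, but 12 pan-leukocyte genes such as Coro1a and Laptm5, listed before their values but after those of T cell genes and Ptprc were seen, had a median log2 fold change of 0.76 (quartiles 0.58 and 0.97), against 1.65 for the 67 genes of the 3 lists. The list medians were 2.12 for interferon-gamma, 1.68 for type I interferon and 1.10 for MHC class I. The class I median exceeded the leukocyte median by less than the margin set in advance for the 3 lists together. For class I genes alone, a higher share of leukocytes therefore stays open. H2-K1, H2-D1 and B2m together rose from 1219 to 3094 CPM, and the 12 leukocyte genes together from 278 to 430 CPM. Chromosome-wide shifts are argued against by their size: the largest upward chromosome median was 0.258, that of chromosome 1, against 1.65 for the 67 genes. The median of 1.58 for the 67 genes after the shifts were subtracted follows from this size and is no separate test. A changed state or mix of leukocytes, interferon signaling in the cancer cells, and a direct effect of Mcrs1 stay open, since bulk tissue does not tell which cells carry the transcripts.

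For the shifts of chromosomes 18, 1 and 11, random sets of genes matched on expression reached the chromosome 18 median with a share of 1e-04, the smallest that 10000 draws can give, and the median was -0.536 (0.212 and 0.164 for chromosomes 1 and 11) after GC content and transcript length were fitted, which argues against chance placement and sequence bias. If a copy number difference between the injected cell lines were the source, all parts of chromosome 18 would be lower in each tumor, and all 16 medians of 4 consecutive parts with about equal numbers of genes in the 4 Mcrs1ox tumors were below -0.2, between -0.76 and -0.30. That is consistent with cells of unequal chromosome 18 dosage, as a hypothesis found and tested on the same data, and chromosomes 1 and 11 were not divided in this way. The line difference coincides with Mcrs1 overexpression and no DNA was analysed here, so part of the 181 genes called lower on chromosome 18 may follow the line's history and not Mcrs1.

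The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, chosen after their values were seen, fell from 339 ± 54.5 to 135 ± 50.4 CPM and from 596 ± 122 to 159 ± 28.2 CPM. A loss of mitochondrial transcripts in general is argued against by the 12 measured mitochondrial mRNAs, whose median log2 fold change was 0.152 (quartiles -0.05 and 0.37). Less carry-over of RNA without poly(A) tails may contribute: 80 small nuclear, nucleolar and other such RNA genes had a median of -0.207, just short of the bound of -0.2 set in advance for excluding it. Their 25th percentile of -0.550 lies above the -1.33 and -1.90 of the ribosomal RNAs, but 66 of the 80 have an average log2 CPM under 1, near the filter, so that percentile does not decide. The others, all small nucleolar RNAs, had log2 fold changes from -0.55 (Snora28) to 0.31 (Gm22579). None of them fell as far as the ribosomal RNAs. They are a single class of RNA, set apart after the values were seen, so they do not decide whether carry-over was the whole cause. Near the filter some RNAs fell further, such as Gm25043 (-7.17). A difference in mitochondrial RNA processing linked to Mcrs1 was not tested.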
